A study of Mus musculus with 6 samples.

How the data were processed

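Messenger RNA was sequenced from mouse hearts in 6 libraries, 3 from flox control mice and 3 from Ythdc1 CKO mice, grouped by their titles. Per the labels' protocols, RNA was selected with poly-T beads and primed with random hexamers, fragments of 370 to 420 bp were kept, and both ends were read for 150 bp; strand marking is not described there. The deposited values are FPKM for 54532 genes, 1 column per library. Per the submitters' processing notes, the authors used CASAVA, HISAT2 2.0.5, featureCounts 1.5.0-p3 and DESeq2 1.20.0 with the build GRCm38.p6; the notes do not say which step made which value. FPKM multiplied by the deposited gene length gave whole multiples of 1 step per library in every gene and library, within a tolerance of 0.001, so the reads behind the deposited FPKM could be recovered. Their totals were 17748541, 17956077 and 19011019 in flox controls 1, 2 and 3 and 17434296, 17872221 and 19360428 in CKO 1, 2 and 3. The denominators of the deposited FPKM equalled the geometric mean of these totals times a median-of-ratios size factor. Gene IDs were compared with the GENCODE release M21 annotation, where 54495 were found and 53585 had identical bounds.

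Choices of test, filter, gene lists, named genes and alternatives were made before the data were examined, except where a test is said to be chosen later. Genes with a mean of at least 1 FPKM over the 6 libraries (12144) were tested on log2(FPKM + 1) with limma 3.58.1 in R 4.3.3, with a variance trend, genotype as the only factor and Benjamini-Hochberg adjusted p under 0.05, 2-sided. Log2 fold changes are on the log2(FPKM + 1) scale, which understates changes of low genes; folds given without log2 are ratios of mean FPKM. Ythdc1 was also tested with an exact 2-sided permutation test over 20 arrangements. In all, 39 gene lists were defined, and those with at least 5 measured members, the sex-linked list apart, were tested with camera at a preset correlation of 0.01, adjusted over 35 lists. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.

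Genes named are Ythdc1, the 10 largest increases and decreases among called genes with non-overlapping groups and an established symbol, up to 4 members of each list with the smallest adjusted p (or 2 where none passed), and 20 genes fixed by name; not all of them are described, and some are not reported here. Other genes are said to be chosen after their values were seen. Reads of overlapping genes on opposite strands cannot be told apart here, which leaves Nppa, Myh6, Myh7, Gabpa, Ndufs1, mt-Tq, mt-Nd6, Idh3b, Sucla2, Snrnp70, Ckmt2, Igf2r, Cidea, Pln and Mettl3 uncertain to the extent of their partners, and Tnni3 and Xirp1 overlap genes on the same strand.

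The procedure was tested on simulated data for the comparison of CKO with flox control, with 200 changed genes over 5 draws and a mean of 12146 genes per fit. It recovered 83.8% of 2-fold and 99% of 4-fold changes, and 6% of calls were false. The simulated spread was smoothed over the mean level, equal in both groups and independent between genes. Real CKO libraries varied more among themselves (correlations 0.955 to 0.977) than flox controls (0.978 to 0.984). These rates therefore need not hold for the real data. Of 40 simulated lists, the 1 list with raised members was called and 0 unchanged lists were called. Members of these lists were drawn at random from genes simulated independently. The simulation therefore does not show how camera treats lists whose members vary together. Alternatives covered the pseudocount (0.1 and 0.01), the filter (none, or a mean of at least 5 FPKM), 4 scalings, 3 variance settings, voom on recovered reads, the replicate number as a block, protein-coding genes only, stricter thresholds, each library left out in turn, and camera with an estimated correlation and fry for lists. Counts of called list members without flox control 2 and without CKO 3 were added after the data were seen, as was a rescaling of every library to the same sum with the 12144 genes kept. Splicing, polyadenylation and m6A marks were not analysed here.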

Results

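Messenger RNA was measured in hearts of mice carrying floxed Ythdc1 alleles without deletion (flox control, 3 libraries) and of mice with conditional knockout of Ythdc1 (CKO, 3 libraries). Ythdc1 encodes a nuclear reader protein of N6-methyladenosine (m6A), a base modification of messenger RNA. The series text writes HKO where the sample labels write CKO, and both were read as the knockout. The labels give 15 days of normal chow and describe the animals as independent biological replicates; age and sex are not in the labels. The comparison asks which cardiac transcripts differ when Ythdc1 is deleted. Gene-assigned reads, recovered from the FPKM values, numbered between 17434296 and 19360428 per library. Pearson correlations of log2(FPKM + 1) were 0.978 to 0.984 between flox control libraries, 0.955 to 0.977 between CKO libraries and 0.940 to 0.953 between the groups. The first principal component (50.8% of variance) separated the groups, and the second (21.9%) set CKO 1 apart from the other CKO libraries.

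The libraries differed in ways the labels do not describe. CKO 3 held 4037 Xist reads, against 0 to 5 in the others, and 0.350 FPKM of Y-linked Ddx3y, against 10.8 to 15.9 FPKM, so its sex-linked expression was that of a female and the other 5 libraries had that of males. No test was made on the sex-linked list. Atrial light chain transcripts were low in CKO libraries and also in 1 control: Myl7 measured 154, 56.6 and 244 FPKM in flox controls 1, 2 and 3, and 39.2, 24.1 and 40.7 FPKM in CKO 1, 2 and 3. These genes were singled out after their values were seen. Mitochondrially encoded genes took 18.4% to 21% of reads in flox controls and 20.7%, 14.4% and 19.6% in CKO 1, 2 and 3.

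**Figure D1:**
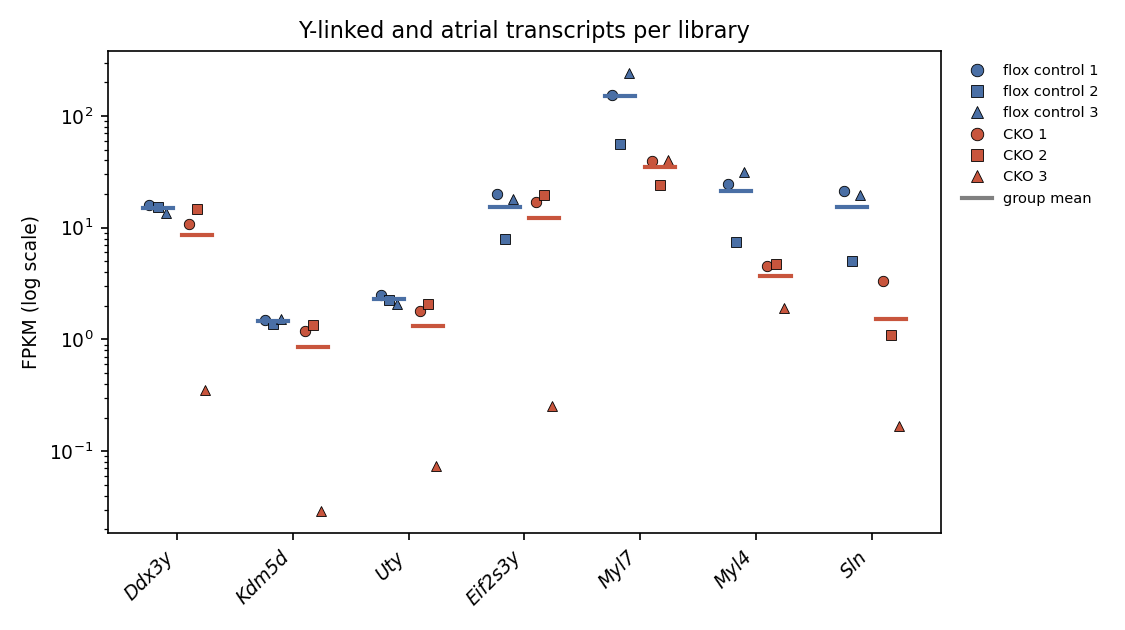
Levels of 4 Y-linked and 3 atrial transcripts in each library, as FPKM on a log axis; points are libraries, colors are groups, shapes are replicate numbers and lines are group means. CKO 3 lies at 0.350 FPKM of Ddx3y, and flox control 2 (56.6 FPKM of Myl7) lies nearest to the CKO libraries.

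Ythdc1 (ENSMUSG00000035851, GRCm38 chromosome 5, 86804221 to 86836659, plus strand) measured 4.31, 3.64 and 4.11 FPKM in flox controls 1, 2 and 3 and 2.39, 2.57 and 2.35 FPKM in CKO 1, 2 and 3, from 580 to 1117 reads per library. The means were 4.02 ± 0.344 and 2.44 ± 0.119 FPKM (SD, n = 3 each), so CKO hearts held 0.607 times the control level. The log2 fold change on the log2(FPKM + 1) scale was -0.54 (SE 0.09, limma adjusted p = 0.015), and every CKO library lay below every control. An exact two-sided permutation test gave p = 0.1, the smallest value that 3 against 3 libraries allow. The value sums all exons of the gene, including any outside the deleted part, and the labels name neither the deleted part nor the cells in which it was deleted. The call was lost without flox control 1 (adjusted p = 0.0707), flox control 3 (0.0637) or CKO 3 (0.0535). It was also lost with the replicate number as a block (0.0542) and after rescaling to TPM, which also tested 14557 genes in place of 12144 (0.0944). Rescaling every library to the same sum with the 12144 genes kept, an alternative chosen after the data were seen, lost it too (0.0888). Over all alternatives tried the adjusted p lay between 0.00825 and 0.0944.

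CKO hearts differed from flox controls in 1358 of 12144 genes tested (limma, adjusted p under 0.05), 691 higher and 667 lower. The change was at least 1 on the log2 scale in 196 higher and 168 lower genes. All 1358 called genes had non-overlapping groups, as did 4169 genes (34.3%) of those tested, where chance gives 10%. Among the largest increases, Gdf15, a stress-induced cytokine, rose from 0.717 ± 0.206 to 18.7 ± 3.99 FPKM, and Serpina3n, a secreted protease inhibitor, from 0.959 ± 0.207 to 24.8 ± 8.88 FPKM. Ankrd1, a stretch-responsive muscle ankyrin protein, rose from 245 ± 54.0 to 2396 ± 695 FPKM, and Ctgf, a matricellular growth factor, from 24.8 ± 9.11 to 227 ± 36.8 FPKM. Acta1, the skeletal alpha-actin gene, had the largest log2 fold change (4.42, SE 0.89, adjusted p = 0.0279) with wide spread: 36.0, 198 and 41.3 FPKM in controls and 516, 1538 and 3807 FPKM in CKO. Its coding sequence resembles those of other actin genes, which leaves some uncertainty in its level. The cardiac actin gene Actc1 went the other way without passing (log2 fold change -0.348, limma adjusted p = 0.41). Wisp2 (14.3-fold), Phgdh (16.2-fold), Krt18 (26.5-fold), Tpm2 (7.99-fold) and Nppa (9.38-fold) completed the 10 named increases, with these 5 folds given as ratios of mean FPKM and the Nppa value being uncertain because an antisense gene overlaps it.

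Counts of called genes depended on the libraries included. They were 315, 602 and 472 without flox control 1, 2 and 3, and 1490, 715 and 579 without CKO 1, 2 and 3. All 1358 fold changes kept their sign in each of these fits, which was fixed in advance because their groups do not overlap. The Acta1 call was lost without flox control 1 (adjusted p = 0.105), flox control 3 (0.093), CKO 2 (0.0784) or CKO 3 (0.0679), and the Nppa call without flox control 2 (0.0666) or 3 (0.0691). With no filter on low values, 32 of 95 calls among the genes covered by the naming rule were lost, among them Acta1 (limma adjusted p = 0.0707), Nppa (0.0514), Nppb (0.0513), Pla2g5 (0.0513), Sln (0.105), mt-Tq (0.0756), Tnni3 (0.218) and Atp2a2 (0.11).

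**Figure D2:**
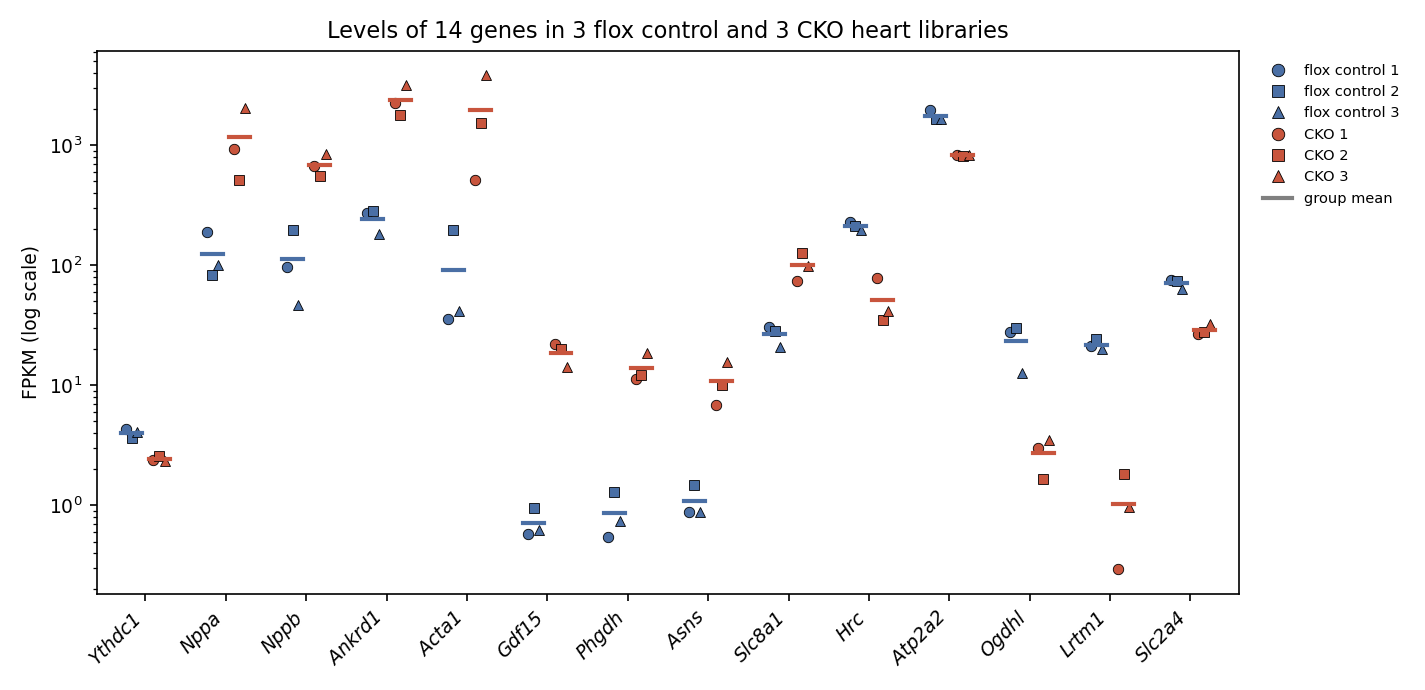
FPKM of 14 named genes in the 6 heart libraries on a log axis; points are libraries, colors are groups, shapes are replicate numbers and lines are group means. Gdf15 went from a mean of 0.717 to 18.7 FPKM and Lrtm1 from 21.9 to 1.02 FPKM, with no overlap between groups.

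Among the largest decreases, Lrtm1, a leucine-rich repeat membrane protein gene, fell from 21.9 ± 2.19 to 1.02 ± 0.761 FPKM, and Rtn4r, the Nogo receptor gene, from 10.6 ± 4.52 to 0.305 ± 0.0594 FPKM. Slc36a2, an amino acid transporter gene, fell from 6.28 ± 0.489 to 0.191 ± 0.0851 FPKM (log2 fold change -2.61, adjusted p = 0.00057). Ogdhl, which encodes an oxoglutarate dehydrogenase-like enzyme, fell from 23.5 ± 9.46 to 2.73 ± 0.960 FPKM, and Klhl33 from 5.41 ± 0.658 to 0.259 ± 0.0836 FPKM. Rpl3l, the striated muscle paralog of ribosomal protein L3, fell from 39.1 ± 5.53 to 7.82 ± 2.98 FPKM. Pla2g5, Sln and the mitochondrial tRNA gene mt-Tq were also among the 10. The mt-Tq value is uncertain, since that gene overlaps mt-Ti on the opposite strand and its lowest library held 2 reads. Calls of these 3 genes were lost without flox control 1 (adjusted p = 0.073, 0.143 and 0.0897 for Pla2g5, Sln and mt-Tq), flox control 3 (0.0667, 0.132 and 0.0894), CKO 2 (0.0546, 0.111 and 0.0827) or CKO 3 (0.0553, 0.111 and 0.0874), and that of Pla2g5 also without flox control 2 (0.0634).

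Gene lists fixed before the data were examined were tested with camera, and 13 of 35 lists passed with its preset correlation, 6 higher and 7 lower. None passed with an estimated correlation (limma camera, lowest adjusted p = 0.223), where 2 lists had an unadjusted p under 0.05, and 5 passed with the rotation test fry. Those 5 were the fetal and stress (fry adjusted p = 0.00805), p53 target (0.0463), integrated stress response (0.0463), ion channel (0.0479) and epicardial lists (0.0479). The epicardial list had not passed with camera. The other lists called by camera did not pass with fry, among them tricarboxylic acid cycle (0.0699), extracellular matrix (0.134), oxidative phosphorylation (0.198) and fatty acid oxidation genes (0.393). In a test chosen after the results were seen, groupings of the 6 libraries that do not follow genotype gave up to 20 called lists. A list call at the preset correlation therefore does not by itself set the genotypes apart. The counts of single genes that follow come from the limma test over all 12144 genes. Of these genes 11.2% were called, and member counts near that share do not set a list apart. Leaving out 1 library leaves 3 residual degrees of freedom, and the counts of called members were then mostly lower.

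**Figure D3:**
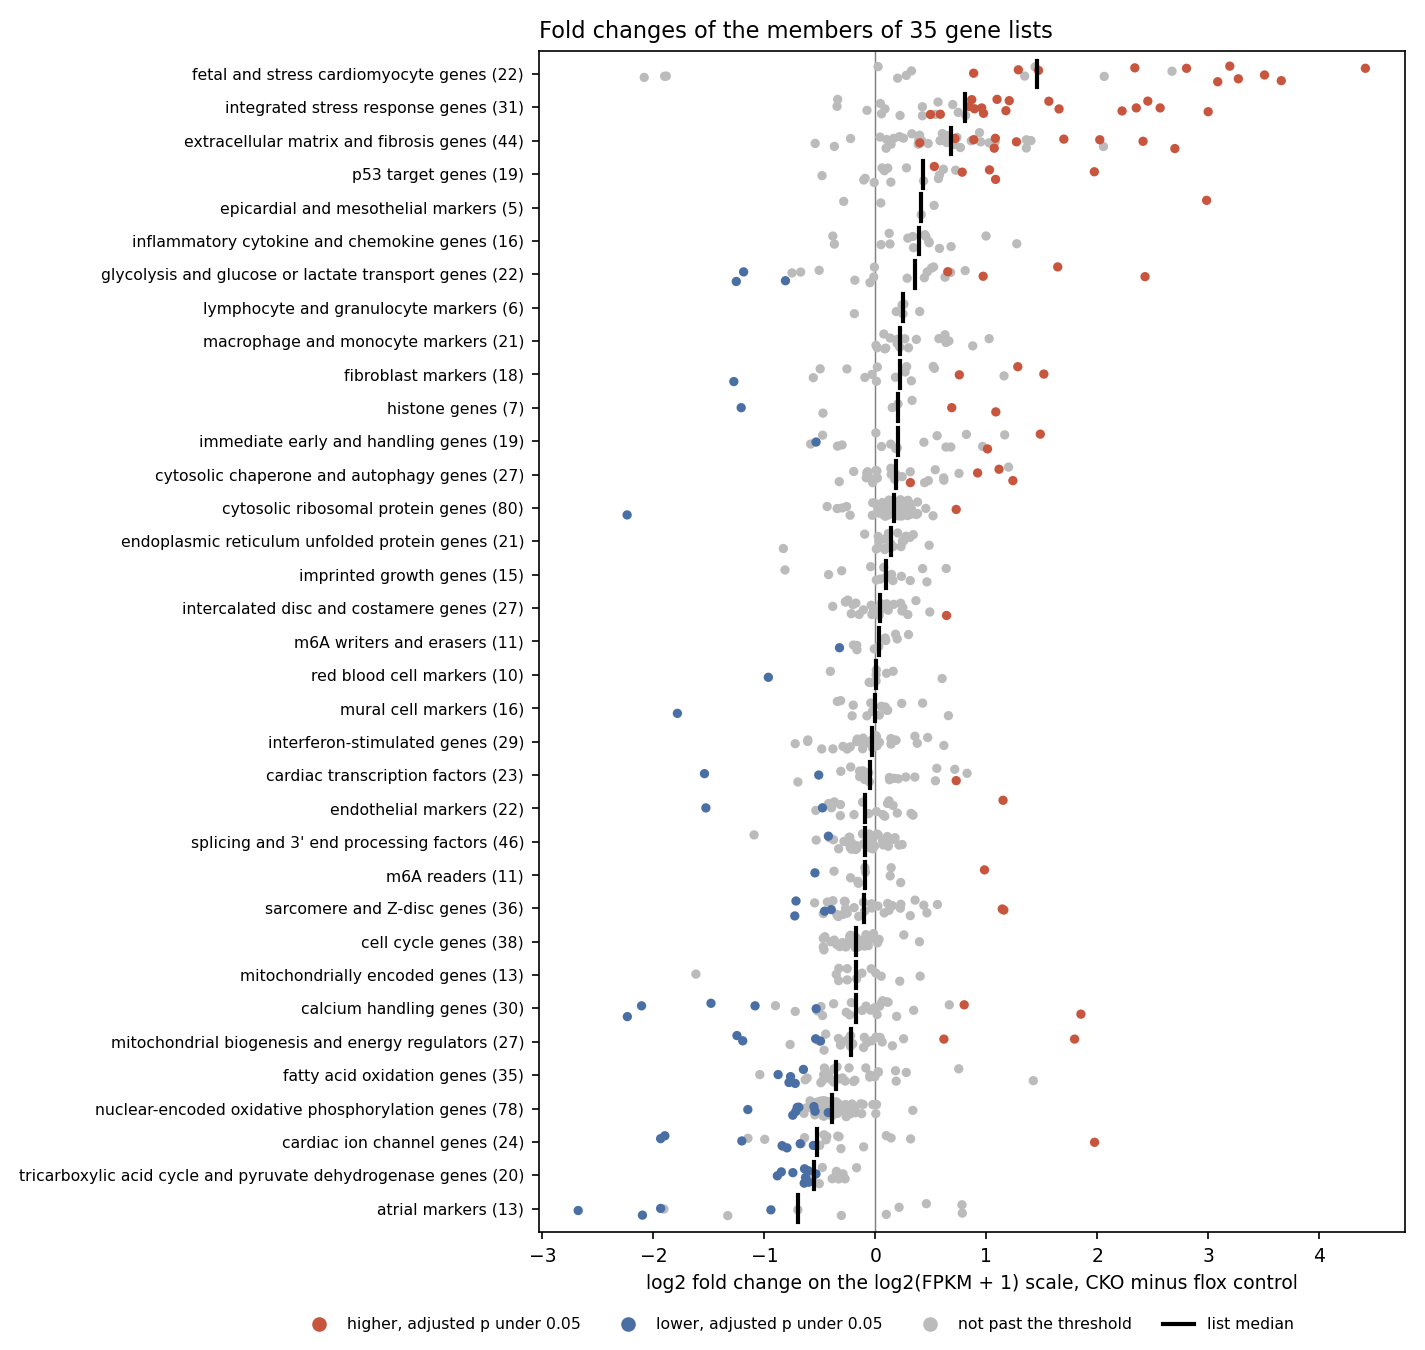
Log2 fold changes (CKO minus flox control, log2(FPKM + 1) scale) of the measured members of 35 gene lists, with the number measured in parentheses; each point is a gene and each black bar the list median. The median is 1.46 for fetal and stress cardiomyocyte genes and -0.55 for tricarboxylic acid cycle genes.

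The list of fetal and stress genes of cardiomyocytes was called higher in CKO hearts. Of 22 measured members, 11 rose, none fell and 11 did not pass; adjusted over the list alone, 15 were higher and 3 lower (camera adjusted p = 3.67e-06, with adjusted p = 0.223 with an estimated correlation). Nppa, which encodes atrial natriuretic peptide, rose from 125 ± 57.9 to 1170 ± 796 FPKM, and Nppb, which encodes B-type natriuretic peptide, from 113 ± 76.5 to 689 ± 150 FPKM. Myh7, the slow myosin heavy chain gene, measured 21.9 ± 1.5 and 128 ± 115 FPKM and did not pass (adjusted p = 0.0871), though it did without CKO 2 (0.0297) and after rescaling to the same sum (0.0449). Mhrt, antisense to Myh7, went the other way (log2 fold change -1.32), and reads of the pair cannot be told apart without strand. The Nppb call was lost without flox control 1 (0.0753) or CKO 3 (0.0608), and that of Nppa without flox control 2 (0.0666) or 3 (0.0691). Members called higher numbered 5, 6 and 6 without flox control 1, 2 and 3, and 14, 7 and 6 without CKO 1, 2 and 3, while 2 were called lower without flox control 2 and 1 without CKO 1.

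Sarcomere genes moved both ways. Of 36 measured members, 2 rose, 4 fell and 30 did not pass, with the same counts adjusted over the list alone (camera adjusted p = 0.354). Flnc, the filamin C gene, rose from 30.3 ± 4.25 to 68.2 ± 9.43 FPKM, and Tnni3, the cardiac troponin I gene, fell from 1357 ± 37.4 to 823 ± 85.8 FPKM. Myh6 (3844 ± 268 and 3212 ± 675 FPKM, adjusted p = 0.482) and Ttn (25.3 ± 3.27 and 20.7 ± 2.30 FPKM, adjusted p = 0.237) did not pass. Without CKO 3 the list passed as lower (0.0154), and members called lower numbered 1, 0 and 0 without flox control 1, 2 and 3 and 1, 1 and 2 without CKO 1, 2 and 3. Tnni3 lost its call without flox control 1 (0.125), 2 (0.0879), 3 (0.101), CKO 1 (0.0716) or CKO 2 (0.069). Of 27 intercalated disc and costamere genes, 1 rose and 26 did not pass, with the same count adjusted over the list alone (camera adjusted p = 0.801). That gene, Xirp1, rose from 39.1 ± 2.62 to 61.5 ± 2.11 FPKM, and lost its call without flox control 1 (0.0519).

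The integrated stress response list was called higher in CKO hearts. Of 31 measured members, 17 rose and none fell, and 24 were higher adjusted over the list alone (camera adjusted p = 6.89e-11, with adjusted p = 0.761 with an estimated correlation). Phgdh and Psat1, which encode enzymes of serine synthesis, and Asns, which encodes asparagine synthetase, were among them. Phgdh rose from 0.866 ± 0.393 to 14 ± 3.93 FPKM, Psat1 from 1.60 ± 0.577 to 12.2 ± 2.05 FPKM and Asns from 1.08 ± 0.343 to 10.9 ± 4.48 FPKM. Trib3, a pseudokinase gene induced by ATF4 and CHOP, rose from 1.72 ± 0.284 to 16.2 ± 8.23 FPKM. Calls of these 4 genes held without each library in turn. Members called higher numbered 7, 12 and 8 without flox control 1, 2 and 3, and 22, 9 and 10 without CKO 1, 2 and 3. Of 21 endoplasmic reticulum unfolded protein genes, none passed over all genes or adjusted over the list alone (camera adjusted p = 0.0946); Herpud1 measured 58.3 ± 13.4 and 32.4 ± 7.77 FPKM and Xbp1 18.1 ± 0.570 and 22.2 ± 1.41 FPKM. That list passed as higher without CKO 3 (0.00112), and Herpud1 as lower after rescaling to the same sum (0.0359).

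The p53 target list and the chaperone and autophagy list were also called higher. Of 19 p53 target genes, 5 rose and 14 did not pass, and 7 were higher adjusted over the list alone (camera adjusted p = 0.00254, with adjusted p = 0.687 with an estimated correlation). Dcxr rose from 1.92 ± 0.154 to 5.02 ± 1.15 FPKM and Phlda3 from 17.3 ± 2.43 to 38.2 ± 9.61 FPKM. Of 27 chaperone and autophagy genes, 4 rose and 23 did not pass, and 5 were higher adjusted over the list alone (camera adjusted p = 0.00541, with adjusted p = 0.898 with an estimated correlation). Hsp90aa1 rose from 29.9 ± 2.54 to 57.7 ± 6.65 FPKM, and Hspb1, a small heat shock protein gene, from 170 ± 30.8 to 400 ± 37.8 FPKM. Dcxr (0.0519), Phlda3 (0.0768) and Hspb1 (0.0505) lost their calls without flox control 1, and Phlda3 (0.0637) without flox control 3. Called p53 targets numbered 0, 3 and 3 without flox control 1, 2 and 3, and 2 and 2 without CKO 2 and CKO 3; called chaperone and autophagy genes numbered 1, 2 and 2 without flox control 1, 2 and 3.

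Lists of mitochondrial energy genes encoded in the nucleus were called lower in CKO hearts by camera at the preset correlation, though none passed with fry. All 20 tricarboxylic acid cycle and pyruvate dehydrogenase genes had negative fold changes, 9 of them past the threshold and 14 adjusted over the list alone (camera adjusted p = 3.22e-08, with adjusted p = 0.847 with an estimated correlation). Idh3b, an isocitrate dehydrogenase subunit gene, fell from 191 ± 10.9 to 103 ± 8.06 FPKM, and Sucla2, a succinyl-CoA ligase subunit gene, from 163 ± 15.6 to 90.1 ± 9.73 FPKM. Of 78 nuclear-encoded oxidative phosphorylation genes, 75 had negative fold changes and 8 fell, with 11 lower adjusted over the list alone (camera adjusted p = 1.58e-11, with adjusted p = 0.847 with an estimated correlation). Ndufs1, a complex I subunit gene, fell from 80.4 ± 7.33 to 48.8 ± 7.64 FPKM, a value left uncertain by Eef1b2 on the opposite strand. Of 35 fatty acid oxidation genes, 5 fell and 30 did not pass, with 6 lower and 1 higher adjusted over the list alone (camera adjusted p = 0.00161, with adjusted p = 0.898 with an estimated correlation). Etfa, an electron transfer flavoprotein subunit gene, fell from 261 ± 33.5 to 153 ± 17.1 FPKM, while Cpt1b measured 3.44 ± 0.591 and 3.36 ± 1.14 FPKM (adjusted p = 0.906). The member counts rested on all 6 libraries. Called tricarboxylic acid cycle genes numbered 1, 2 and 3 without flox control 1, 2 and 3 and 3, 2 and 6 without CKO 1, 2 and 3; called oxidative phosphorylation genes numbered 0 without any 1 flox control and 2, 1 and 6 without CKO 1, 2 and 3. Called fatty acid oxidation genes numbered 0, 0 and 1 without flox control 1, 2 and 3 and 0 without CKO 2 or CKO 3. The fatty acid oxidation list was no longer called without flox control 1 (0.0589). Single calls were lost for Sucla2 without flox control 1 (0.0637), for Ndufs1 without flox control 1 (0.104), 2 (0.071), 3 (0.0705) or CKO 2 (0.0726), and for Etfa without flox control 1 (0.11), 2 (0.084), CKO 2 (0.0667) or CKO 3 (0.0535).

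Regulators of mitochondrial biogenesis and energy use included genes that changed in each direction. Of 27 measured members, 2 rose, 4 fell and 21 did not pass, with 2 higher and 8 lower adjusted over the list alone (camera adjusted p = 0.0188, with adjusted p = 0.847 with an estimated correlation). Dio2, a thyroid hormone activating deiodinase gene, rose from 0.566 ± 0.164 to 4.54 ± 1.31 FPKM, and Gabpa, a transcription factor gene, fell from 10.7 ± 0.524 to 7.03 ± 0.177 FPKM, a value left uncertain by Atp5j on the opposite strand. Ppargc1a measured 22.8 ± 10.7 and 18.3 ± 5.33 FPKM (adjusted p = 0.747). None of the 13 mitochondrially encoded genes passed over all genes or adjusted over the list alone (camera adjusted p = 0.54); mt-Nd3 measured 204 ± 57.6 and 80.8 ± 68.0 FPKM, passing without CKO 1 (0.0114), and mt-Nd6, which overlaps mt-Nd5, 16450 ± 1580 and 13130 ± 3198 FPKM. Of 22 glycolysis and glucose or lactate transport genes, 4 rose, 3 fell and 15 did not pass, with 6 higher and 4 lower adjusted over the list alone (camera adjusted p = 0.359). Slc2a4, the insulin-responsive glucose transporter gene, fell from 70.5 ± 6.09 to 29.1 ± 3.21 FPKM, and Slc2a1, the basal glucose transporter gene, rose from 3.14 ± 0.503 to 12.5 ± 4.71 FPKM. Without flox control 1 the regulator list (0.0774), Gabpa (0.055) and Slc2a1 (0.0623) lost their calls, as did the regulator list without CKO 2 (0.0584) and Slc2a1 without flox control 3 (0.0596) or CKO 3 (0.0535). The glycolysis list passed as higher without CKO 1 (0.0261). Regulators called lower numbered 0 and 1 without flox control 1 and 2, and 2 and 2 without CKO 2 and CKO 3. Glycolysis genes called higher numbered 0, 2 and 0 without flox control 1, 2 and 3 and 9 and 1 without CKO 1 and CKO 3.

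The calcium handling and ion channel lists were called lower in CKO hearts, although most of their members did not pass. Of 30 calcium handling genes, 2 rose, 5 fell and 23 did not pass, with 3 higher and 12 lower adjusted over the list alone (camera adjusted p = 0.0337, with adjusted p = 0.847 with an estimated correlation). Atp2a2, which encodes the sarcoplasmic reticulum calcium pump, fell from 1748 ± 179 to 821 ± 2.01 FPKM (log2 fold change -1.08, SE 0.15, adjusted p = 0.0106). Hrc, a sarcoplasmic reticulum calcium-binding protein gene, fell from 214 ± 17.2 to 51.8 ± 23.1 FPKM, and Slc8a1, the sodium-calcium exchanger gene, rose from 26.6 ± 5.07 to 99.7 ± 26.2 FPKM. Ryr2 measured 40.6 ± 5.12 and 24.5 ± 5.48 FPKM (adjusted p = 0.0543) and Pln 509 ± 71.3 and 284 ± 104 FPKM (adjusted p = 0.0984). Of 24 cardiac ion channel genes, 1 rose, 7 fell and 16 did not pass, with 1 higher and 11 lower adjusted over the list alone (camera adjusted p = 6.56e-05, with adjusted p = 0.687 with an estimated correlation). Kcnd2, a transient outward potassium channel gene, fell from 4.11 ± 0.919 to 0.384 ± 0.352 FPKM. Without flox control 1 the calcium list (0.0589) and Atp2a2 (0.0573) lost their calls, the calcium list did so without CKO 1 (0.0806), and Pln passed without CKO 1 (0.037). Calcium genes called lower numbered 2, 3 and 3 without flox control 1, flox control 3 and CKO 3, and ion channel genes called lower numbered 2, 3 and 2. Kcnj3 (log2 fold change -1.935) counts among both the ion channel genes and the atrial markers, and the ion channel list had its lowest adjusted p among fits with 1 library left out without flox control 2 (5.86e-06), whose Myl7 lies nearest to the CKO libraries.

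The extracellular matrix list was called higher in CKO hearts by camera at the preset correlation, though not by fry (adjusted p = 0.134). Of 44 measured members, 10 rose, none fell and 34 did not pass, with 17 higher and 1 lower adjusted over the list alone (camera adjusted p = 3.22e-08, with adjusted p = 0.847 with an estimated correlation). Bgn, the biglycan gene, rose from 57.0 ± 6.13 to 141 ± 28.8 FPKM. Thbs4, the thrombospondin 4 gene, rose from 2.95 ± 1.32 to 25.9 ± 12 FPKM. Col1a1 (121 ± 21.1 and 195 ± 65.2 FPKM, adjusted p = 0.148), Col3a1 (194 ± 16.3 and 212 ± 53 FPKM, adjusted p = 0.792) and Postn (42.6 ± 6.78 and 96.5 ± 54.2 FPKM, adjusted p = 0.138) did not pass. Matrix genes called higher numbered 1, 4 and 5 without flox control 1, 2 and 3, and 22 and 4 without CKO 1 and CKO 3. Bgn (0.0519) and Thbs4 (0.0548) lost their calls without flox control 1, and Postn passed without CKO 1 (0.0321).

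Markers of other heart cells did not pass as lists. Of 18 fibroblast markers, 3 rose and 1 fell, with 4 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.18). Tcf21, a fibroblast transcription factor gene, rose from 6.89 ± 0.913 to 18.6 ± 5.02 FPKM, and lost its call without flox control 1 (0.0633), flox control 2 (0.0555) or CKO 3 (0.0517). Of 22 endothelial markers, 1 rose and 2 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.204); Vwf rose from 5.20 ± 1.47 to 12.6 ± 2.44 FPKM, and lost its call without flox control 2 (0.0622) or CKO 3 (0.0581). Of 16 mural cell markers only Vtn passed, also adjusted over the list alone, falling from 17.6 ± 2.37 to 4.66 ± 2.35 FPKM (camera adjusted p = 0.743), with its call lost without flox control 1 (0.0594) or 3 (0.0513). Of 21 macrophage and monocyte markers none passed over all genes or adjusted over the list alone, though all 21 fold changes were positive (camera adjusted p = 0.18); Lgals3 measured 1.81 ± 0.750 and 5.24 ± 3.61 FPKM. Fibroblast markers called higher numbered 0, 1 and 1 without flox control 1, 2 and 3 and 1 without CKO 3, and endothelial markers called lower 0, 1 and 0 without flox control 1, 2 and 3 and 0, 1 and 0 without CKO 1, 2 and 3. The fibroblast list passed as higher without CKO 2 (0.0327), the endothelial list as lower without CKO 2 (0.0252) and the macrophage list as higher without CKO 3 (0.000911), whereas without CKO 1 the macrophage list turned to lower without passing (mean log2 fold change -0.22, adjusted p = 0.228).

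Some atrial markers were lower in CKO hearts. Of 13 measured members, 4 fell and 9 did not pass, with 5 lower and 1 higher adjusted over the list alone (camera adjusted p = 0.139); the list passed as lower without flox control 2 (0.017) and after rescaling to the same sum (0.037). Sln, which encodes sarcolipin, measured 21.1, 5.05 and 19.8 FPKM in flox controls 1, 2 and 3 and 3.34, 1.09 and 0.168 FPKM in CKO 1, 2 and 3, the last from 4 reads. Stard10 fell from 7.96 ± 2.88 to 1.06 ± 0.614 FPKM and Kcnj3 from 6.71 ± 1.57 to 1.04 ± 0.592 FPKM. Atrial genes called lower numbered 1 without flox control 1, and 2 and 2 without CKO 2 and CKO 3. Stard10 lost its call without flox control 1 (0.053), and Sln without flox control 1 (0.143), flox control 3 (0.132), CKO 2 (0.111) or CKO 3 (0.111). Of 5 epicardial and mesothelial markers 1 rose, also adjusted over the list alone (camera adjusted p = 0.125): Krt18, a keratin gene, from 0.409 ± 0.223 to 10.8 ± 4.79 FPKM. That list passed as higher with fry (adjusted p = 0.0479), and with camera without CKO 1 (0.0491) or CKO 3 (0.0355).

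Few genes of the m6A pathway and of RNA processing were called. Of 11 m6A readers, Igf2bp2 rose from 1.33 ± 0.337 to 3.61 ± 0.594 FPKM and Ythdc1 fell, with 1 higher and 2 lower adjusted over the list alone (camera adjusted p = 0.586); the mean of this list was positive after rescaling to TPM, where more genes were tested (0.10). Of 11 m6A writers and erasers, Wtap fell from 6.93 ± 0.117 to 5.34 ± 0.146 FPKM, also adjusted over the list alone (camera adjusted p = 0.998), and Mettl3, the catalytic writer gene, measured 2.47 ± 0.241 and 2.54 ± 0.0541 FPKM (adjusted p = 0.864). Of 46 splicing and 3' end processing factors, only Snrnp70 passed, falling from 29.7 ± 0.732 to 21.9 ± 0.877 FPKM, with 0 adjusted over the list alone. That list was called lower by camera (adjusted p = 0.0428, with adjusted p = 0.847 with an estimated correlation), and its call was lost without flox control 1 (0.0589), flox control 3 (0.108), CKO 1 (0.0801) or CKO 3 (0.102), and after rescaling to the same sum (0.128). Srsf3 (adjusted p = 0.0985), Srsf10 (0.905), Cpsf6 (0.945) and Rbm20 (0.322) did not pass. Igf2bp2 lost its call without flox control 3 (0.0504). Wtap lost its call without flox control 1 (0.124), 2 (0.084), 3 (0.12), CKO 1 (0.0632), CKO 2 (0.0901) or CKO 3 (0.0828), and Snrnp70 without flox control 1 (0.0977), 2 (0.0691), 3 (0.0949), CKO 2 (0.0669) or CKO 3 (0.063).

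Among 23 cardiac transcription factors, Gata4 rose from 39.2 ± 1.68 to 65.9 ± 9.06 FPKM, while Hopx fell from 148 ± 25.3 to 50.7 ± 11.4 FPKM and Nkx2-5 from 54.3 ± 4.30 to 37.9 ± 4.18 FPKM. The counts were the same adjusted over the list alone (camera adjusted p = 0.912), and the list median (-0.05) and mean (0.03) differed in sign; 3 members were called higher without CKO 1, 0 without any 1 flox control, and 1 lower without each library in turn. Gata4 lost its call without flox control 1 (0.0759), 2 (0.0587) or 3 (0.0555), and Nkx2-5 without flox control 1 (0.0962), 2 (0.111), 3 (0.134), CKO 1 (0.0743), CKO 2 (0.0958) or CKO 3 (0.0573). Of 80 cytosolic ribosomal protein genes, Rps27 rose and Rpl3l fell, also adjusted over the list alone, and the list was called higher (camera adjusted p = 0.00327, with adjusted p = 0.943 with an estimated correlation; 0.244 without flox control 1). Rps27 is uncertain, since its near-identical copy Rps27rt fell (log2 fold change -1.90), and it lost its call without flox control 1 (0.0519), 2 (0.0666), 3 (0.0772) or CKO 3 (0.0574).

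Genes of dividing cells, of blood cells and of interferon and cytokine responses gave few calls. Of 38 cell cycle genes none passed over all genes or adjusted over the list alone (camera adjusted p = 0.282), and 34 fold changes were negative; Cenpf measured 1.38 ± 0.198 and 0.820 ± 0.697 FPKM and Cdt1 2.44 ± 0.986 and 1.53 ± 0.860 FPKM. The list passed as lower without CKO 1 (0.00612) or CKO 2 (0.0485) and as higher without CKO 3 (0.0273). Of 29 interferon-stimulated genes none passed over all genes or adjusted over the list alone (camera adjusted p = 0.586); Cmpk2 measured 5.01 ± 1.52 and 3.05 ± 1.38 FPKM, and Ifi27 passed as lower without CKO 1 (0.011). That list passed as lower without CKO 1 (0.00163) and as higher without CKO 3 (0.0134). None of 16 inflammatory cytokine and chemokine genes passed over all genes or adjusted over the list alone (camera adjusted p = 0.345, and 0.00768 as higher without CKO 3); Vcam1 measured 2.46 ± 0.0775 and 4.79 ± 2.02 FPKM and passed without CKO 3 (0.0409). None of 6 lymphocyte and granulocyte markers passed over all genes or adjusted over the list alone (camera adjusted p = 0.736). Of 10 red blood cell markers, Tfrc, the transferrin receptor gene, fell from 119 ± 8.40 to 60.6 ± 8.04 FPKM, also adjusted over the list alone (camera adjusted p = 0.63), with a list median of 0.01 and a mean of -0.06. In the limma test, members with an unadjusted p under 0.05 numbered 0 among cell cycle, interferon-stimulated and lymphocyte genes, 2 among inflammatory genes, 2 among imprinted genes, 1 among macrophage markers, 1 among mitochondrially encoded genes and 4 among unfolded protein genes.

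Immediate early genes, which respond to tissue handling, included 2 higher and 1 lower of 19 measured, with 3 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.139, and 0.0392 and 0.00742 as higher without flox control 2 and 3). Members called higher numbered 1, 3 and 5 without flox control 1, 2 and 3 and 2, 1 and 2 without CKO 1, 2 and 3; 1 was called lower without CKO 1 and 0 without any other 1 library. Ier3 rose from 18.1 ± 3.24 to 52.1 ± 4.05 FPKM. None of 15 imprinted growth genes passed over all genes or adjusted over the list alone (camera adjusted p = 0.359); Plagl1 measured 3.39 ± 0.394 and 5.93 ± 1.55 FPKM. Imprinted genes called numbered 2 higher without CKO 1, 1 lower without CKO 2 and 1 higher without CKO 3, the last being Igf2r (0.0475). Only 7 of 70 listed histone genes reached a mean of 1 FPKM in these poly-T selected libraries. Of these 7, 2 rose and 1 fell, also adjusted over the list alone (camera adjusted p = 0.586). Hist2h2be fell from 4.34 ± 0.499 to 1.31 ± 0.155 FPKM, and Hist1h1c rose from 40.4 ± 5.07 to 87.3 ± 15.6 FPKM, with its call lost without flox control 1 (0.0519). Histone genes called higher numbered 0, 1 and 1 without flox control 1, 2 and 3 and 1 without CKO 3. Lists of tissues other than heart had too few members above 1 FPKM for a test: 0 fast skeletal muscle genes, 3 Schwann and neuronal markers and 2 fat, lung, liver and thymus markers. Of the Schwann and neuronal markers Prnp rose and Dbh fell, also adjusted over the list alone; the fat, lung, liver and thymus markers Ager and Cidea passed as higher adjusted over the list alone, and over all genes without CKO 1 (0.017 and 0.0213), Cidea also after rescaling to the same sum (0.0449). The Prnp call was lost without flox control 1 (0.143), 2 (0.101), 3 (0.133), CKO 2 (0.0976) or CKO 3 (0.0547), and the Dbh call without flox control 1 (0.0874), flox control 3 (0.0732), CKO 2 (0.0586) or CKO 3 (0.0662).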

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

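Counts of list members without flox control 2 and without CKO 3, and the rescaling to the same sum with the genes kept, were tests chosen after the data were seen; the other alternatives were planned. All 1358 called genes kept the direction of change under every alternative in which they were tested, 836 of them at a mean of at least 5 FPKM and 1216 among protein-coding genes. Non-overlapping groups fixed this in advance for fits that changed the pseudocount or filter or left out a library. The count of called genes stayed between 924 and 1695 with pseudocounts of 0.1 or 0.01, a mean of at least 5 FPKM, the other scalings, variance settings, array weights, voom on recovered reads (1427, of which 1260 were shared) and protein-coding genes only. It moved to 798 (388 higher, 410 lower) with no filter, which tests 27031 genes. Rescaling to TPM, which moved the filter to 14557 genes, gave 567 higher and 439 lower genes. Rescaling to the same sum with the 12144 genes kept gave 565 higher and 424 lower genes. By construction, an adjusted p under 0.01 gave 252 (127 higher, 125 lower) and an absolute log2 fold change of at least 1 gave 364 (196 higher, 168 lower).

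Leaving out 1 library gave 315 to 1490 called genes, 160 to 807 higher and 155 to 683 lower; the lower counts were 315, 602 and 472 without flox control 1, 2 and 3, and 715 and 579 without CKO 2 and CKO 3. Each such fit has 1 fewer residual degree of freedom. Of 95 called genes covered by the naming rule, 63 stayed past the threshold with no filter, 80 after rescaling to TPM, 82 after rescaling to the same sum with the genes kept and 58 with the replicate number as a block. Of the same 95, 37, 61 and 53 stayed past the threshold without flox control 1, 2 and 3, and 82, 61 and 59 without CKO 1, 2 and 3. The lists called numbered 8 (without flox control 1) to 19, against 13 with all libraries, 0 with an estimated correlation (2 at an unadjusted p under 0.05) and 5 with fry. The log2 fold change of Ythdc1 was -0.60 to -0.50 when 1 library was left out, with the call lost without flox control 1 (adjusted p = 0.0707), flox control 3 (0.0637) or CKO 3 (0.0535). It was -0.58 after rescaling to TPM (0.0944) and -0.50 after rescaling to the same sum (0.0888; range over alternatives 0.00825 to 0.0944), and the cause was not tested. Ythdc1 lies below a mean of 5 FPKM and has no value there.

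With the replicate number as a block, 715 genes were called (367 higher, 348 lower), 664 of them shared, and 13 lists; the log2 fold change of Ythdc1 was -0.54 (adjusted p = 0.0542). Deviations from the group means of libraries with the same number correlated at 0.139, 0.06 and -0.005, and flox control 3 correlated best with CKO 2 (0.141). With 3 libraries per group these values neither show nor exclude a pairing of the libraries.

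A change of sign, or a turn of a list's test direction, was seen only in genes and lists that had not passed with all libraries, and the cause was not tested. After rescaling to TPM, Srsf10 was at 0.027 (0.026 at the same sum with the genes kept) and the mean log2 fold change of the m6A reader list at 0.10. With no filter the red blood cell list was at 0.012. The test direction alone turned, with no change of sign of the mean, for writers and erasers with pseudocounts of 0.1 (0.001) and 0.01 (0.0), with no filter (0.003) and after rescaling to TPM (0.05), for histone genes with no filter (0.002) and for inflammatory cytokine genes at a mean of at least 5 FPKM (0.034). The fry direction of cardiac transcription factors differed from their mean (0.028). Leaving out 1 library gave ranges that crossed 0 for Cd79b (-0.013 to 0.327), Csf3r (-0.158 to 0.835), Col3a1 (-0.041 to 0.323), Ppargc1a (-0.625 to 0.088), Cpt1b (-0.253 to 0.056), Srsf10 (-0.074 to 0.029), Cpsf6 (-0.061 to 0.052) and Mettl3 (-0.027 to 0.070). List means did so for writers and erasers (-0.031 to 0.024), mitochondrially encoded genes (-0.40 to 0.14), mural (-0.20 to 0.03), macrophage (-0.22 to 0.77), lymphocyte (-0.20 to 0.63) and red blood cell markers (-0.17 to 0.03), cell cycle (-0.41 to 0.22), interferon-stimulated (-0.43 to 0.34), inflammatory (-0.07 to 0.72), cardiac transcription factor (-0.029 to 0.083) and imprinted genes (-0.092 to 0.155). For intercalated disc genes the mean stayed positive (0.004 to 0.075) while the test direction turned.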

Other observations

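Tests on splits of the libraries for gene lists, on tricarboxylic acid cycle genes, on atrial markers and on long non-coding genes were chosen after the results were seen, as was the count of autosomal genes called without CKO 3. The tests on atrial tissue for the lower genes and on the sex of CKO 3 were prompted by transcript levels in single libraries and written before their own results were seen; the other tests were planned.

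Of 27 called genes for long intergenic non-coding RNA (lincRNA) 22 were lower in CKO hearts (81.5%), against 573 of 1216 called protein-coding genes (47.1%). The 2-sided Fisher exact test of these counts (p = 0.000358) was run on the called genes that prompted it, so it decides nothing. Of 412 called protein-coding genes with a mean of up to 4.94 FPKM, a bound taken from the called lincRNA genes, 197 were lower (47.8%). The Fisher exact test against the lincRNA genes (p = 0.000624) uses the same 27 genes, so it does not decide on low expression as the explanation. Genes are not independent replicates, so a lower level of this class in CKO hearts may be kept only as a hypothesis. Of 177 lincRNA genes tested, 15.3% were called, and the median log2 fold change over those tested was -0.09, against 0.01 in protein-coding genes.

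Transcription factor genes were called less often than other protein-coding genes, 62 of 705 (8.8%) against 1154 of 10168 (11.3%, 2-sided Fisher exact p = 0.0357), the opposite of the hypothesis tested. Genes are not independent replicates and expression level was not matched, so the lower share settles nothing about this class. Near Ythdc1, 9 of 50 genes (18.0%) were called, against 1348 of 12093 elsewhere (11.1%; Fisher exact p = 0.171), and genes linked to the floxed locus by strain cannot be told apart from other changed genes there.

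For the 1358 called genes, other groupings of the libraries gave at most 1 called gene; with 10 splits the share of 1 in 10 is too coarse for a threshold of 0.05. Of 1317 autosomal called genes, 544 (41.3%) were also called without CKO 3, when all libraries left had male expression. These calls argue against the sex of CKO 3 as the source, for these 544 genes. All 1358 called genes kept an unadjusted p under 0.05 (limma) without CKO 3, but they were selected with it. That they kept their sign was fixed in advance by their non-overlapping groups. Of 568 autosomal genes called without CKO 3, 565 moved the same way in it. Both sides share the controls, so the share expected without a change is not known. The median ratio of fold changes without and with CKO 3 was 0.968 (95% interval 0.960 to 0.972) over the autosomal called genes. The ratio alone is weak evidence, since genes that differ in 1 library are hardly called. Fold changes were nearly unrelated to gene length (Spearman rho across genes -0.01354, up to 0.2484 in size in other splits) and to GC content (0.04335, up to 0.09834). The difference in genotype that the labels name stays open as the biological explanation and is untested beyond these comparisons. For the lists, 13 were called in the real split, 7 of the 10 splits called at least as many and the highest other called 20. The number of list calls at the preset correlation therefore does not set the genotypes apart. With 10 splits a share under 0.05 could not be reached either.

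Less atrial tissue in the CKO libraries was weighed for the lower genes, since Myl7, Myl4 and Sln in flox control 2 lay 0.71, 0.67 and 0.55 of the way from the other controls to the CKO mean. Some other atrial transcripts that were lower in CKO hearts lay at 1.16 (Bmp10), 0.38 (Stard10) and 0.26 (Kcnj3). Mybphl (log2 fold change -1.905), Myl1 (-0.941), Tbx5 (-0.698) and Nr2f1 (-0.306) also had negative fold changes but were not placed. Of the 13 measured members of the atrial list, 5 had positive and 8 negative fold changes, and no member with a positive one was placed. Over 298 genes called lower without that library, its median position was 0.132 (95% interval 0.105 to 0.162). The interval lies under 0.5, the bound set beforehand, and under the 6 markers placed. Myl1 was not among them and showed no such shift in flox control 2. The interval argues against less atrial tissue as the source of the lower genes as a whole, although the position rests on 1 library and on chosen markers. For the atrial markers themselves the median position was 0.61 over the 6 chosen markers, Myl1 not among them. Less atrial tissue cannot be told apart there from a change within cells, since flox control 2 prompted the test.

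A lower cardiomyocyte share of the RNA was weighed for the lower calcium handling and tricarboxylic acid cycle genes. Median log2 fold changes were -0.09 for endothelial (95% interval -0.35 to 0.1), 0.00 for mural (-0.2 to 0.1) and 0.22 for fibroblast markers (-0.06 to 0.53). They were not all above 0, the pattern set beforehand for a lower share, and none lay below 0 with its interval. A rise of only 1 other cell type would not meet that pattern, so these medians do not decide. Fibroblast markers minus endothelial markers differed by 0.312 in median log2 fold change (95% interval -0.072 to 0.708), so for calcium handling genes a lower share cannot be told apart from a change within cells, as the intervals span 0. Macrophage markers lay at 0.22 (0.2 to 0.57), above endothelial markers, but their mean was -0.22 without CKO 1. Tricarboxylic acid cycle genes lay -0.449 from sarcomere genes in median log2 fold change (95% interval -0.632 to -0.203 over genes), where a lower share of cardiomyocytes would lower both alike. The sarcomere list itself passed as lower without CKO 3 (camera adjusted p = 0.0154). A change within cardiomyocytes is a candidate explanation for the tricarboxylic acid cycle genes, which these intervals over genes cannot settle.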
